A study of Mus musculus with 8 samples.

How the data were processed

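RNA was measured in CD4+ effector T cells carrying a congenic marker, about 10000 per sample, sorted 6 weeks after transfer into Rag1-/- mice, which have no T or B cells of their own. The transferred cells carried a retroviral short hairpin against Mdr1, the multidrug transporter encoded by Abcb1a, or a control hairpin against CD8. Cells came from the lamina propria of the small intestine or from the spleen, and the hosts either had or lacked Asbt (Slc10a2), the bile acid transporter of the ileum. With 3 factors of 2 levels each and 1 library per combination, there were 8 libraries. The hairpin was taken from the sample titles, because another label field names the Mdr1 hairpin for all 8 libraries. Per the labels' protocols, libraries were made with an ultra-low-input SMART-Seq kit, which amplifies full-length cDNA without molecular identifiers, and a NEBNext kit.

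The deposited values are raw read counts per gene, 1 column per library, in whole numbers. Per the submitters' processing notes, TopHat, HTSeq and DESeq2 were used with the mouse build mm9. Versions, roles, the gene annotation and the strand setting are not given in the sources used here, so counts of overlapping genes, antisense genes and near-identical paralogs are uncertain. These include the hemoglobin genes, Abcb1a with Abcb1b, Reg3b with Reg3g, Bcl2a1a with Bcl2a1b, Il22 with Iltifb, and Defa24. No coordinates are given. Gene symbols are those of the count table, and 36174 of its 37411 symbols occur in the GENCODE vM21 table of names.

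Of the 37411 genes in the table, 17570 had at least 1 count. The filterByExpr function of edgeR, applied to the additive design, kept 10000 genes, which held 99.52% of the counts. Counts were scaled with TMM factors and fitted with the edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3). The Benjamini-Hochberg adjustment was applied over all tested genes at a threshold of 0.05. The SE given after ± on a log2 fold change is the one implied by the quasi-likelihood F statistic. It is the absolute log2 fold change divided by the square root of F, and is approximate. The effects of tissue, hairpin and host were tested in an additive fit of all 8 libraries, with 4 libraries per level and 4 residual degrees of freedom. The libraries of a level thus stand as replicates over the other factors, and the residual spread holds interactions as well as library noise. Tissue-dependent hairpin and host effects, and the effects within a tissue (2 libraries against 2), came from a fit with separate effects in each tissue, with 2 residual degrees of freedom. Host-dependent hairpin effects came from a fit with that interaction, with 3 residual degrees of freedom. The labels do not say that the libraries came from separate animals or which libraries shared an animal. All p-values therefore measure the spread between these libraries, which may be partly technical.

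In addition, 28 gene lists were tested, covering T cell programmes, stress and metabolic pathways, and markers of other cells. The 26 lists with at least 5 tested genes were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in one direction and does not compare them with other genes. For each hairpin pair of one tissue and host, which has no replicate, log2 CPM ratios with a prior count of 2 are given without a test. List medians of these pairs were ranked among 10000 random lists of equal size matched on mean expression.

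The design, tests, lists and rules for naming genes were fixed before the data were examined. In each tested comparison, up to 8 genes per direction were named by fold change among those past the threshold that had a mean CPM of at least 10 in the higher level and the same direction in every matched library pair. Genes without a proper name and antigen receptor segments were left out of that rule. Up to 4 passing members of each list were named, by smallest p. Abcb1a, Abcb1b, Cd8a, Cd8b1, Slc10a2, Nr1i3, Ifng, Tnf, Il17a, Il10, Tbx21, Foxp3 and Hmox1 were always reported; 1 further gene of this rule is not reported here. Where fewer than 10 genes passed, the 5 genes with the smallest p in each direction were added as values that did not pass. For the pairs, up to 6 genes per direction with at least 100 counts were named. Any other gene in the text was chosen after its values were seen.

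Alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, limma-voom, no covariates, fits of 1 tissue alone, another prior count of 10, and leaving out each library. Fits without both small intestine Asbt+/+ libraries, with library quality weights, without hemoglobin, mitochondrial and Rn18s-rs5 counts, and with a block for each matched library pair (libraries alike in the other 2 factors, 3 residual degrees of freedom) were added after the data were seen.

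Total counts per library ran from 1685225 to 2767105. A count of 0 in a library allows up to 3 counts, which is 1.18 to 1.93 CPM. For genes with a level at 0 in all its libraries, folds are lower bounds against 3 counts over that level. Where a level had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Shares of counts in a library carry 95% Wilson intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

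The tests were checked on simulated data with 10000 genes, 200 of them changed, 50 at each fold size. Changed genes were drawn from those with a mean of at least 10 CPM. Genes were independent, without interactions, and each gene had the same spread in every library. The real libraries differed in quality, with quality weights from 0.131 to 2.441, so these shares and false calls may not hold for them. For the comparison of tissues, edgeR recovered 4% of genes changed 2-fold, 50% at 4-fold, 76% at 8-fold and 94% at 16-fold, with 8 unchanged genes called. For hairpins the shares were 2%, 36%, 66% and 90%, with 2 unchanged genes called. For hosts they were 6%, 54%, 78% and 88%, with 8 unchanged genes called. In the 2 against 2 comparison of hairpins in spleen, edgeR recovered 0%, 18%, 52% and 74%, with 4 unchanged genes called. For hosts in small intestine the shares were 2%, 24%, 60% and 74%, with 11 unchanged genes called. DESeq2 called 46, 42 and 42 unchanged genes in the tissue, hairpin and host simulations.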

Results

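The data are raw gene counts from 8 RNA-seq libraries of CD4+ effector T cells recovered 6 weeks after transfer into T cell-deficient hosts. Libraries carried the shMdr1 or the control shCD8 hairpin, came from small intestine lamina propria or spleen, and came from Asbt+/+ or Asbt-/- hosts. There was 1 library for each combination, so each level of a factor held 4 libraries. In small intestine, totals were 1685225 counts for shMdr1 Asbt+/+, 2417913 for shCD8 Asbt+/+, 2767105 for shMdr1 Asbt-/- and 2375872 for shCD8 Asbt-/-. In spleen they were 2250491 for shMdr1 Asbt+/+, 2135056 for shCD8 Asbt+/+, 1821772 for shMdr1 Asbt-/- and 2100582 for shCD8 Asbt-/-.

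The shCD8 small intestine Asbt+/+ library had counts for 8456 genes, while the other 7 libraries had counts for 11345 to 13184. Of 3151 genes at 20 CPM or more in each of the other 7 libraries, 49 had no count in it (1.56%, 95% Wilson interval 1.18 to 2.05%), and no other library had such a gene. Its mean Spearman correlation with the others was 0.696, against 0.774 to 0.846. Mitochondrial transcripts took 18.3% of the counts (18.25 to 18.37%) in shMdr1 small intestine Asbt+/+, 26.8% (26.72 to 26.85%) in shMdr1 spleen Asbt-/- and 17.6% (17.55 to 17.65%) in shCD8 spleen Asbt-/-. In the remaining 5 libraries they took 6.63 to 8.63%. Hemoglobin transcripts took 3.69% (3.67 to 3.72%) in shMdr1 spleen Asbt-/- and 0.109 to 0.554% in the other spleen libraries. They took 0.017% or less in small intestine.

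**Figure D1:**
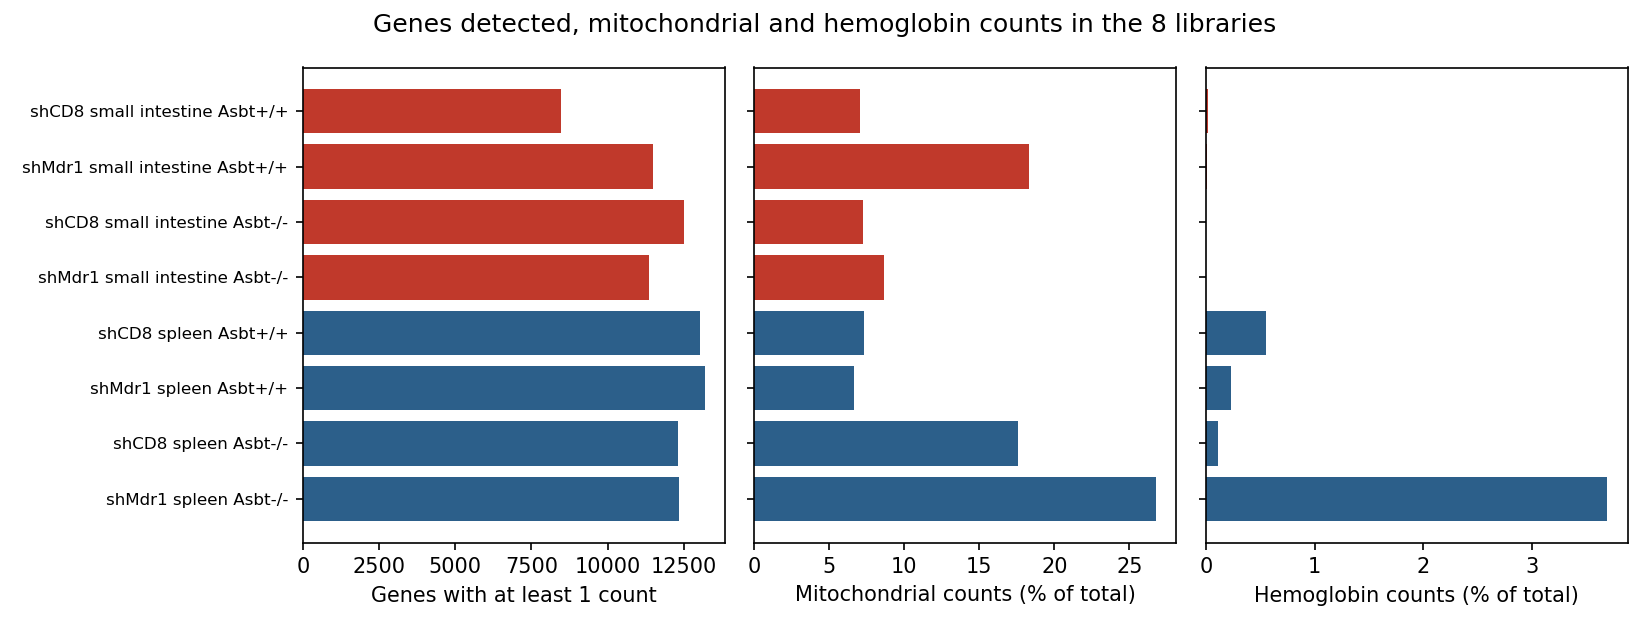
Horizontal bars show, for each of the 8 libraries, the number of genes with at least 1 count, the percentage of counts from mitochondrial genes and the percentage from hemoglobin genes (red, small intestine; blue, spleen). The shCD8 small intestine Asbt+/+ library has 8456 genes, and hemoglobin reaches 3.69% in the shMdr1 spleen Asbt-/- library.

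Abcb1a, the gene encoding the targeted transporter, was lower with shMdr1 than with shCD8 in 3 of the 4 pairs of one tissue and host. In small intestine of Asbt-/- hosts it had 102 counts with shMdr1 and 228 with shCD8, in spleen of Asbt+/+ hosts 45 and 95, and in spleen of Asbt-/- hosts 36 and 62. In small intestine of Asbt+/+ hosts it had 23 counts (14.8 CPM) with shMdr1 and 21 (8.28 CPM) with shCD8, so that pair goes against its labels. In the additive fit its log2 fold change was -0.75 ± 0.61 (SE), which did not pass the edgeR test (adjusted p = 0.999). Its paralog Abcb1b stood at -0.27 ± 0.74, lower in 2 of 4 pairs (adjusted p = 0.999, edgeR). Cd8a, a target of the control hairpin, had 150 counts with shMdr1 and 0 with shCD8 in small intestine of Asbt+/+ hosts. It had 70 and 57 in small intestine of Asbt-/- hosts, and 31 and 7 in spleen of Asbt+/+ hosts. Both spleen libraries of Asbt-/- hosts had 0. Slc10a2, the gene absent from the Asbt-/- hosts, had 3 counts in shCD8 spleen Asbt-/-, 1 in shMdr1 small intestine Asbt-/- and 0 in the other 6 libraries. Nr1i3, a nuclear receptor for bile acids and xenobiotics, had no count in any of the 8 libraries.

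The comparison of small intestine with spleen asks how transferred cells differ between a tissue exposed to bile acids and a lymphoid organ. Cells were isolated from a different organ at each level, so effects of the tissue and of the isolation cannot be told apart. Nr4a3, an orphan nuclear receptor gene induced by T cell receptor signalling, reached 453 ± 108 CPM (mean ± SD, n = 4) in small intestine and 52.6 ± 18.3 CPM in spleen, an 8.83-fold difference (log2 3.14 ± 0.26). Fosl2, an AP-1 transcription factor, was 8.60-fold higher, and Crem, a cAMP-responsive transcription factor, 8.16-fold higher. The cytokine gene Il17a was 5.39-fold higher in small intestine, at 1317 ± 771 against 236.7 ± 124 CPM (log2 2.43 ± 0.27). Ccr9, the chemokine receptor that directs T cells to the small intestine, was 9.37-fold higher (log2 3.23 ± 0.50). In the edgeR test, adjusted p was 0.000611 for Nr4a3, 0.00224 for Fosl2, 0.00152 for Crem, 0.00224 for Il17a and 0.0180 for Ccr9, and each gene had the same direction in 4 of 4 pairs.

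Across 10000 tested genes, 62 passed the edgeR test, 51 higher in small intestine and 11 higher in spleen, each with the same direction in 4 of 4 pairs. All 62 kept their direction when any 1 library was left out, and 11 passed in all 8 such fits. Those 11 were Crem, Dgat1, Fosl2, Il17a, Il1r2, Litaf, Nr4a1, Nr4a3 and Penk, higher in small intestine, and S100a9 and Wfdc21, higher in spleen. The count of 62 became 12 without shMdr1 small intestine Asbt+/+, 145 without shCD8 small intestine Asbt+/+, 38 without shMdr1 small intestine Asbt-/- and 40 without shCD8 small intestine Asbt-/-. It became 27 without shMdr1 spleen Asbt+/+, 34 without shCD8 spleen Asbt+/+, 25 without shMdr1 spleen Asbt-/- and 22 without shCD8 spleen Asbt-/-. DESeq2 called 257 genes, including all 62.

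Of 21 immediate early genes, 5 passed the test over all genes as higher in small intestine: Nr4a3, Nr4a1 (5.23-fold), Nr4a2 (4.38-fold), Fosl2 and Egr2 (5.54-fold). Adjusted over the list alone, 7 were higher and 1 lower. Limma's camera gave the list adjusted p = 1.51e-06, and adjusted p = 0.0619 with an estimated correlation. Among 15 inhibitory receptors and exhaustion genes, 4 were higher, including Ctla4, an inhibitory receptor (3.58-fold), and Cd160 (5.59-fold); Nr4a1 and Nr4a2 are in both lists. Adjusted over the list alone, 6 were higher (camera adjusted p = 9.26e-07, and adjusted p = 0.0619 with an estimated correlation). None of the 21 lists called by camera in this comparison kept its call with an estimated correlation, while fry called 10.

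Among 17 effector cytokines, Il17a and Tnfsf11, which encodes RANKL (4.12-fold), passed the edgeR test as higher in small intestine, and 4 were higher when adjusted over the list alone (camera adjusted p = 6.96e-06, and adjusted p = 0.0643 with an estimated correlation). In the type 17 helper programme 1 of 18 genes passed, Il17a, and 7 were higher adjusted over the list alone (camera adjusted p = 2.40e-05, and adjusted p = 0.0619 with an estimated correlation). In the type 1 helper programme 1 of 17 genes passed, Gzmb, which encodes a cytotoxic granule protease (3.76-fold), and 7 were higher adjusted over the list alone (camera adjusted p = 1.51e-06, and adjusted p = 0.134 with an estimated correlation). Of 14 regulatory T cell markers, Ctla4, Icos (2.92-fold) and Tnfrsf9 (5.60-fold), all genes that activated effector cells also express, were higher, and 7 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000356, and adjusted p = 0.134 with an estimated correlation). Foxp3, the lineage factor of that list, did not pass. Ifng and Tnf did not pass either.

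Of 21 gut homing and tissue residency genes, Ccr9, Gzma (7.84-fold) and Gzmb passed as higher in small intestine, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 4.50e-05, and adjusted p = 0.0619 with an estimated correlation). The 19 lymphoid homing and naive or memory genes had a median log2 fold change of -0.81, with none passing edgeR over all genes and 2 lower adjusted over the list alone. Camera called this list lower (adjusted p = 0.0172, and adjusted p = 0.241 with an estimated correlation), except without shMdr1 small intestine Asbt+/+ (adjusted p = 0.0652). The 30 cell cycle genes had a median of -1.22, with 26 below 0 and none passing alone or adjusted over the list alone. Camera called them lower in small intestine (adjusted p = 9.17e-05, and adjusted p = 0.402 with an estimated correlation). Without both small intestine Asbt+/+ libraries, a fit added after seeing the data, the cell cycle list was no longer lower (adjusted p = 0.955).

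Of 25 NRF2 and oxidative stress genes, Mt2, a metallothionein (11.9-fold), and Sqstm1, an autophagy adaptor (2.45-fold), passed as higher in small intestine, and 5 were higher adjusted over the list alone (camera adjusted p = 0.000355, and adjusted p = 0.0643 with an estimated correlation). Hspe1, a mitochondrial chaperonin (3.15-fold), passed among 12 heat shock genes, and 5 were higher adjusted over the list alone (camera adjusted p = 7.41e-06, and adjusted p = 0.201 with an estimated correlation). Over the 8 fits that left out 1 library, Mt2 and Hspe1 passed in 1, without shCD8 small intestine Asbt+/+, and Sqstm1 in 0. The 9 bile acid receptor and nuclear receptor target genes had a median of 0.25, with none passing over all genes and 3 higher adjusted over the list alone. Camera called them higher (adjusted p = 0.0173, and adjusted p = 0.201 with an estimated correlation), except without shCD8 spleen Asbt+/+ (0.0983) or without shCD8 small intestine Asbt+/+ (0.152). The unfolded protein response (adjusted p = 0.0539) and the list of Abcb1a and other multidrug transporters (adjusted p = 0.911) were not called by camera.

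The 25 apoptosis regulators had a median log2 fold change of 0.39, with none passing over all genes and 5 higher adjusted over the list alone (camera adjusted p = 0.00285, and adjusted p = 0.259 with an estimated correlation). The 16 glycolysis genes had a median of 0.46, with none passing alone or adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.252 with an estimated correlation). None of 21 cholesterol and lipid uptake genes, 14 CD4 T cell identity genes or 23 ribosomal protein genes passed, alone or adjusted over the list alone. Camera called these as slightly higher in small intestine, with medians of 0.20, 0.13 and 0.26 (adjusted p = 0.0197, 0.0172 and 0.00206, and adjusted p = 0.409, 0.134 and 0.409 with an estimated correlation). The cholesterol call was lost without shMdr1 spleen Asbt-/- (0.0553), shCD8 spleen Asbt-/- (0.199) or shCD8 small intestine Asbt-/- (0.242), the CD4 identity call without shCD8 small intestine Asbt+/+ (0.0959), and the ribosomal call without shMdr1 small intestine Asbt-/- (0.0842). Nuclear genes of oxidative phosphorylation (adjusted p = 0.191) and interferon-stimulated genes (adjusted p = 0.390) were not called by camera.

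Other genes higher in small intestine included Litaf, an endosomal protein gene (11.8-fold), Dgat1, an enzyme of triglyceride synthesis (9.21-fold), Penk, the enkephalin precursor (7.79-fold), and Il1r2, a decoy receptor for interleukin 1 (7.34-fold). The chemokine gene Ccl1 was 16.3-fold higher and Areg, an EGF receptor ligand, 5.07-fold higher. Cxcl9, an interferon-induced chemokine, had 383 counts in small intestine and 2 in spleen, a ratio of 177 (95% counting interval 48.7 to 1470). In the other direction, Itgb1, the integrin beta 1 chain, was 6.95-fold higher in spleen (log2 -2.80 ± 0.47), and the kinase gene Ikbke 4.30-fold higher (log2 -2.10 ± 0.35). All these genes passed the edgeR test, with adjusted p from 0.00224 to 0.0341.

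Some markers of other cells differed between the tissues as well. Tff2, a trefoil peptide of mucosal epithelium, had 533 counts in small intestine and 0 in spleen, at least 164-fold higher, and Defa24, a Paneth cell defensin, had 270 and 0, at least 83.3-fold higher. Of 13 epithelial markers 1 passed, Defa24, and 4 were higher adjusted over the list alone (camera adjusted p = 1.60e-06, and adjusted p = 0.0773 with an estimated correlation). The antigen presentation genes Cd74 (4.38-fold) and H2-Aa (5.50-fold) were higher in small intestine. Of the 11 genes higher in spleen, 9 are neutrophil genes or encode hemoglobin chains. S100a8 was 47.4-fold higher, at 2759 ± 2036 against 65.0 ± 56.6 CPM, S100a9 111-fold and Ngp 243-fold. Camp, an antimicrobial peptide of neutrophil granules, had 3261 counts in spleen and 1 in small intestine (ratio 3520, interval 632 to 139000), Wfdc21 had 695 and 1 (751, interval 134 to 29700), and Lcn2 had 255 and 3 (91.9, interval 31.1 to 448). Hbb-bs was 366-fold (6369 ± 9973 against 10.6 ± 5.02 CPM), Hbb-bt 537-fold (1403 ± 2187 against 1.94 ± 2.21 CPM) and Hba-a2 600.5-fold (1955 ± 3102 against 2.37 ± 1.04 CPM) higher in spleen. Much of the spleen mean came from shMdr1 spleen Asbt-/-: without it the log2 values moved from -8.52 to -6.59 for Hbb-bs, from -9.07 to -6.95 for Hbb-bt and from -9.23 to -7.08 for Hba-a2, and each still passed. Without shMdr1 small intestine Asbt+/+ the values were -8.86, -9.79 and -9.28, and none passed (edgeR adjusted p = 0.0839, 0.0805 and 0.0716). Without shCD8 spleen Asbt+/+, Hbb-bs stood at -7.65 and did not pass (0.053).

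Of 8 erythroid genes, 3 passed as lower in small intestine and 7 were lower adjusted over the list alone (camera adjusted p = 8.41e-08, and adjusted p = 0.134 with an estimated correlation; median log2 -7.85, or -7.15 with genes at 0 set to their bounds). The 19 myeloid and antigen-presenting cell genes had 2 higher and 2 lower, with 5 higher and 2 lower adjusted over the list alone. Camera called that list higher (adjusted p = 0.00859, and adjusted p = 0.319 with an estimated correlation), except without shMdr1 spleen Asbt-/- (0.0861) or shCD8 small intestine Asbt-/- (0.0692). None of 6 stromal and endothelial genes passed, alone or adjusted over the list alone, and camera called the list higher (median log2 3.19, or 2.39 with bounds; adjusted p = 0.000869, and adjusted p = 0.241 with an estimated correlation). The NK and innate lymphoid list was not called (camera adjusted p = 0.165). CD8 T cell and B cell markers had 1 and 3 tested genes, too few for a list test.

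**Figure D2:**
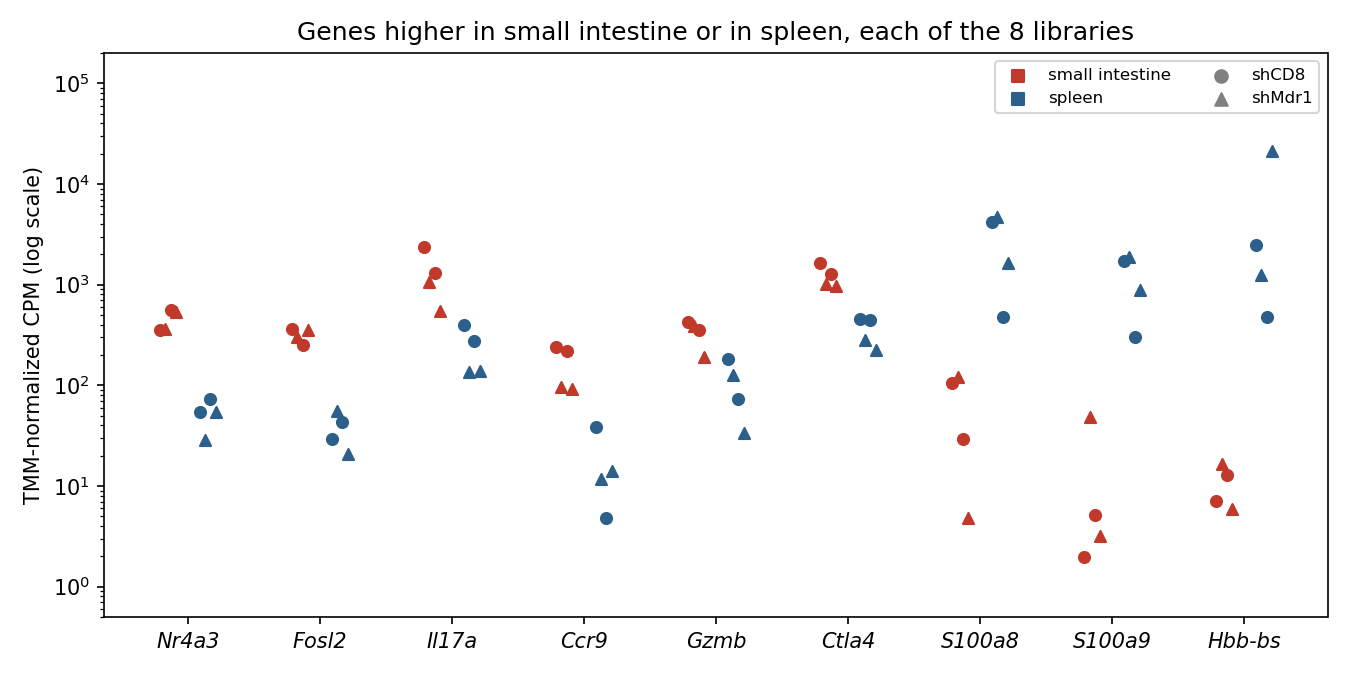
Each point is the TMM-normalized CPM of a gene in 1 library, on a log scale, in red for small intestine and blue for spleen, with circles for shCD8 and triangles for shMdr1. Nr4a3 averages 453 CPM in small intestine and 52.6 CPM in spleen, and S100a8 averages 65.0 and 2759 CPM.

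The comparison of shMdr1 with shCD8 asks what a hairpin against the transporter changes in effector T cells. Il17a averaged 469 ± 435 CPM (mean ± SD, n = 4) with shMdr1 and 1085 ± 973 CPM with shCD8, a log2 difference of -1.22 ± 0.26, lower in 4 of 4 pairs. Foxp3 stood at -2.30 ± 0.96 and Il10, an anti-inflammatory cytokine gene, at -1.38 ± 0.92, each lower in 4 of 4 pairs. Nkg7, a cytotoxic granule gene, stood at 1.37 ± 0.30, with 1690 ± 838 against 622 ± 277 CPM, and Tbx21, the type 1 helper factor, at 1.22 ± 0.50, each higher in 4 of 4 pairs. None of these values passed the edgeR test over all genes (adjusted p = 0.999 for each).

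No gene passed the edgeR test between hairpins, where 299 of 10000 genes had an unadjusted p under 0.05 and chance gives about 500. Limma-voom also called 0. DESeq2 called 3: Il17a (log2 -1.22, adjusted p = 0.0158), Nkg7 (1.36, adjusted p = 0.0158) and Cystm1 (5.68, adjusted p = 0.00292), a gene with 148 of its counts in shMdr1 small intestine Asbt+/+. Other values with the smallest p were Ftl1, the ferritin light chain gene (1.06 ± 0.25), Ict1 (1.27 ± 0.31), Lgals2 (6.52 ± 1.39), Penk (-1.46 ± 0.33), Cxcl3 (-1.63 ± 0.40), Ctss (-0.99 ± 0.25) and Mfsd6 (-2.06 ± 0.52). They held in 4 of 4 pairs, except Cxcl3 in 3 and Lgals2, which had 250 against 1 and 30 against 1 counts in the small intestine pairs and 0 in all spleen libraries. Ifng (0.11 ± 0.42), Tnf (0.58 ± 0.47), Cd8a (1.60 ± 1.43) and Hmox1, an antioxidant enzyme gene (-1.57 ± 1.75), did not pass either.

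Of 14 regulatory T cell markers, 13 had a log2 fold change below 0 with shMdr1, with a median of -0.67, and none passed alone or adjusted over the list alone. Camera gave adjusted p = 2.57e-05, and adjusted p = 0.623 with an estimated correlation, while fry gave adjusted p = 0.662. Effector cytokines had a median of -0.58, with 3 of 17 lower adjusted over the list alone, and were not called by camera (adjusted p = 0.0638). The type 17 helper programme had 2 of 18 lower adjusted over the list alone (camera adjusted p = 0.310), and the type 1 helper programme had 1 of 17 higher (camera adjusted p = 0.523). Lists of CD4 T cell identity (median -0.04, camera adjusted p = 0.727), oxidative stress (camera adjusted p = 0.727) and the unfolded protein response (camera adjusted p = 0.807) were not called.

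**Figure D3:**
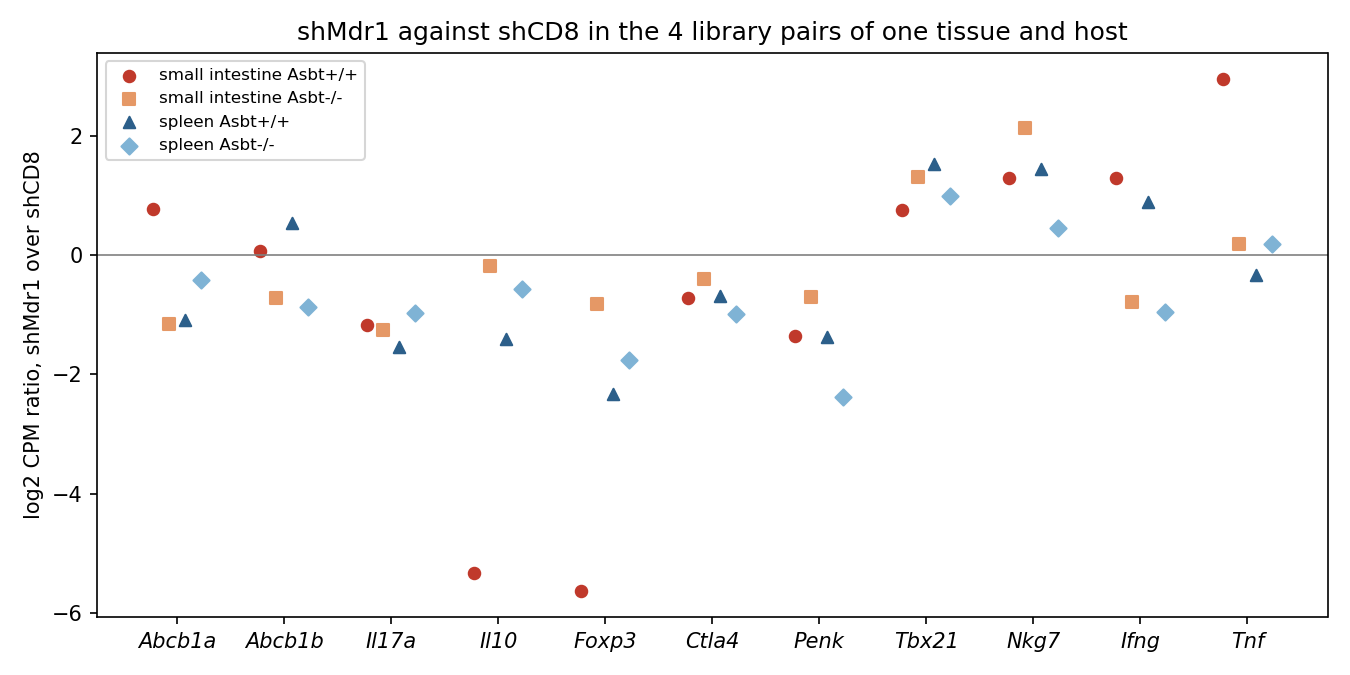
Points are log2 CPM ratios of shMdr1 over shCD8 for 11 genes in each of the 4 pairs of one tissue and host; the grey line marks equal levels. Il17a, Foxp3 and Il10 lie below 0 in 4 of 4 pairs and Tbx21 and Nkg7 above 0 in 4 of 4, and none of these passed the edgeR test.

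The comparison of Asbt-/- with Asbt+/+ hosts asks how T cells differ in hosts that lack the ileal bile acid transporter. Reg3g, an antimicrobial lectin of intestinal epithelium, averaged 1.39 ± 2.77 CPM (mean ± SD, n = 4) in Asbt-/- hosts and 77.9 ± 102 CPM in Asbt+/+ hosts (log2 -6.27 ± 0.79). Its paralog Reg3b stood at -5.28 ± 0.83, and both were lower in 4 of 4 pairs. Both are epithelial genes, and whether the sorted T cells made these transcripts was not tested. Gzma averaged 451 ± 432 against 2038 ± 1806 CPM (log2 -2.24 ± 0.50). In the edgeR test the smallest adjusted p was 0.0721, for Reg3g, followed by 0.281 for Reg3b, and no gene passed.

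With 0 genes called by edgeR, 271 genes had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 6, all lower in Asbt-/- hosts: Gzma, Krt19, Krt8, Reg3b, Reg3g and S100a8. Without shCD8 small intestine Asbt+/+, edgeR called 4, all lower: Agr2, Gpx2, Reg3b and Reg3g. Values with the next smallest p were S100a8 (-2.38 ± 0.53) and AA467197 (-1.77 ± 0.42) in one direction, and Nfkbid (1.12 ± 0.26), Sgk1 (1.44 ± 0.35), Cpm (1.25 ± 0.33), Kdm6b (1.26 ± 0.35) and Birc6 (1.18 ± 0.33) in the other. Il17a stood at -0.59 ± 0.25, Ifng at -0.01 ± 0.42, Foxp3 at 0.81 ± 0.96 and Abcb1a at 1.07 ± 0.65, and none passed.

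Of 13 epithelial markers, 12 were below 0 with a median of -3.55, and 4 were lower adjusted over the list alone. The cells that made these transcripts were not determined, so the values need not describe T cells. Camera called the list (adjusted p = 3.06e-14), with adjusted p = 0.115 with an estimated correlation and fry adjusted p = 0.0558. All 12 heat shock genes were above 0 with a median of 0.50, and none passed alone or adjusted over the list alone. Camera gave heat shock adjusted p = 0.0316, and adjusted p = 0.802 with an estimated correlation. The heat shock call held in 1 of 8 fits that left out a library, without shMdr1 small intestine Asbt-/-, and adjusted p in the other 7 was 0.0630 to 0.112. It was 0.0647 with a block for each matched library pair, a fit added after seeing the data. In those 7 fits the library left out was shMdr1 small intestine Asbt+/+, shCD8 small intestine Asbt+/+, shCD8 small intestine Asbt-/- or any of the spleen libraries.

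Differences between effects were tested directly. A tissue-dependent hairpin effect was called by edgeR for 0 genes (170 with an unadjusted p under 0.05, 1 gene by DESeq2, 0 by limma-voom). Bbip1 (2.68 ± 0.53), Ccl1 (3.27 ± 0.69), Magoh (1.95 ± 0.43) and Med28 (1.72 ± 0.44) lay above 0, and Ifitm1, an interferon-induced membrane protein gene (-4.23 ± 0.88), and Il17f (-5.12 ± 1.38) below. None of them passed. For the tissue-dependent host effect edgeR also called 0 genes (431 unadjusted, 22 by DESeq2, 0 by limma-voom), with the cyclin gene Ccna2 at 5.44 ± 0.84, Ly6c2 at 7.20 ± 1.18, Gzmk at 4.19 ± 0.76 and Abcb1a at 2.57 ± 1.10. For the host-dependent hairpin effect edgeR called 0 (119 unadjusted, 0 by DESeq2, 3 by limma-voom). There Ifng stood at -1.92 ± 0.59, Cd160 at -2.34 ± 0.55, Klrd1 at -2.27 ± 0.68 and Camp at 3.69 ± 0.83.

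Leaving out libraries moved these counts. Without shMdr1 or shCD8 small intestine Asbt+/+ the tissue-dependent hairpin count was 533 or 523, without shMdr1 or shCD8 small intestine Asbt-/- it was 2907 or 2919, and it was 3 or 1 without a spleen library of Asbt+/+ or Asbt-/- hosts. The tissue-dependent host count was 3290, 903, 3277 and 920 without shMdr1 Asbt+/+, shCD8 Asbt+/+, shMdr1 Asbt-/- and shCD8 Asbt-/- of small intestine, and 2 without either shCD8 spleen library. With a small intestine library left out, the spleen libraries alone supply the residual spread, with 1 degree of freedom. The host-dependent hairpin count was 769 without shCD8 spleen Asbt+/+ and 0 without each other library.

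Within small intestine, the tissue exposed to bile acids, Il17a averaged 800.2 CPM with shMdr1 and 1835 CPM with shCD8 (log2 -1.21 ± 0.31, lower in 2 of 2 pairs), and Il17f stood at -4.33 ± 1.05. Bbip1 (2.71 ± 0.39), Magoh (2.08 ± 0.32), Med28 (1.85 ± 0.32), Cst3 (1.83 ± 0.32) and Ict1 (1.87 ± 0.37) lay above 0, and Cetn2 (-1.84 ± 0.35) and Brix1 (-1.86 ± 0.43) below. No gene passed edgeR (481 with an unadjusted p under 0.05, 26 by DESeq2, 0 by limma-voom), and camera called 0 of 26 lists. Regulatory T cell markers had a median of -0.44 (camera adjusted p = 0.311). A fit of the small intestine libraries alone called 7 genes. The count was 847 or 836 without shMdr1 or shCD8 Asbt+/+ of small intestine, 3759 or 3773 without shMdr1 or shCD8 Asbt-/-, and 1 without any spleen library.

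Between hosts within small intestine, 27 of 30 cell cycle genes had a log2 fold change above 0 in Asbt-/- hosts, with a median of 1.53. None passed over all genes. Adjusted over the list alone, 3 were higher, and 0 in the fit of the small intestine libraries alone. Both Asbt+/+ libraries of this contrast stood apart, shMdr1 with 18.3% mitochondrial counts and shCD8 with 8456 genes detected. Camera gave adjusted p = 0.000322, and adjusted p = 0.974 with an estimated correlation; the call was lost without shMdr1 small intestine Asbt+/+ (0.382) or shMdr1 small intestine Asbt-/- (0.387). The 13 epithelial markers had a median of -3.64, with 2 lower adjusted over the list alone (camera adjusted p = 2.63e-07, and adjusted p = 0.974 with an estimated correlation). Abcb1a averaged 65.7 CPM in Asbt-/- and 11.5 CPM in Asbt+/+ hosts (log2 2.45 ± 0.81, 2 of 2 pairs, edgeR adjusted p = 0.624). Ccna2 (4.11 ± 0.65), Gzmk (3.35 ± 0.57) and Tob1 (3.13 ± 0.54) lay above 0, and the linker histone genes Hist1h1e (-3.10 ± 0.53) and H1f0 (-2.28 ± 0.42) below. No gene passed edgeR (743 unadjusted, 65 by DESeq2, 0 by limma-voom, 7 in the small intestine libraries alone). The count was 4108, 1047, 4139 and 1072 without shMdr1 Asbt+/+, shCD8 Asbt+/+, shMdr1 Asbt-/- and shCD8 Asbt-/- of small intestine, and 6 or 7 without a spleen library.

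Within spleen, Ifitm1 (3.79 ± 0.67) and Ifitm2 (2.40 ± 0.66) lay above 0 with shMdr1, and Ccl1 (-3.40 ± 0.53), Fgl2, which encodes a secreted immunoregulatory protein (-2.52 ± 0.59), Penk (-1.93 ± 0.48), Cxcl3 (-2.13 ± 0.58) and Il17a (-1.26 ± 0.32) below, each in 2 of 2 pairs. In the fit of all 8 libraries edgeR called 0 genes (62 unadjusted, 3 by DESeq2, 0 by limma-voom), and the spleen libraries alone, with 1 residual degree of freedom, called 81. Between hosts in spleen, Kdm6b, a histone demethylase gene (1.94 ± 0.39), and the mitochondrial gene mt-Nd5 (1.91 ± 0.40) lay above 0 in Asbt-/- hosts, and Gzmb (-1.62 ± 0.37) and Ccl1 (-2.27 ± 0.52) below. Reg3b had no count in either Asbt-/- spleen library and 87 and 56 counts in the Asbt+/+ spleen libraries with shMdr1 and shCD8. EdgeR again called 0 genes (102 unadjusted, 20 by DESeq2, 0 by limma-voom), and the spleen libraries alone called 149. Mitochondrial transcripts took 26.8 and 17.6% of counts in the Asbt-/- spleen libraries and 6.63 and 7.33% in the Asbt+/+ ones. Leaving out shMdr1 small intestine Asbt-/- raised the counts to 92 for hairpins and 151 for hosts; the other small intestine libraries gave 87 for hairpins, and 147 (shMdr1 Asbt+/+) or 146 for hosts. Without shMdr1 Asbt+/+, shCD8 Asbt+/+, shMdr1 Asbt-/- and shCD8 Asbt-/- of spleen the counts were 4, 4, 1 and 1 for hairpins and 1, 7, 1 and 6 for hosts.

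The hairpin pairs of one tissue and host, which have no replicate, differed widely in spread. Their SD of log2 ratios over 10000 genes was 2.18 in small intestine of Asbt+/+ hosts, 1.27 in small intestine of Asbt-/- hosts, 0.799 in spleen of Asbt+/+ hosts and 1.02 in spleen of Asbt-/- hosts. In small intestine of Asbt+/+ hosts, Foxp3 had 0 counts with shMdr1 and 113 with shCD8, Il17f 3 and 494, Il10 1 and 156, and Gpx2, an intestinal glutathione peroxidase, 485 and 2. In small intestine of Asbt-/- hosts, Foxp3 had 57 and 101, Il4 8 and 121, Tbx21 126 and 49, and the respiratory chain gene Uqcrb 3196 and 312. In spleen of Asbt+/+ hosts, Ifitm1 had 3322 and 99, Gzma 2461 and 359, Klrk1, an activating receptor gene of cytotoxic lymphocytes, 178 and 15, Ccl1 41 and 435, and Il4 25 and 165. In spleen of Asbt-/- hosts, Hbb-bs had 34569 and 1003, Ngp 263 and 12, Cxcl3 81 and 549, and Fgl2 10 and 120. Regulatory T cell markers had a median log2 ratio of -0.95 and -0.83 in the spleen pairs of Asbt+/+ and Asbt-/- hosts, both at percentile 0 of 10000 random lists. Effector cytokines stood at -1.01 (percentile 0) in spleen of Asbt+/+ hosts and -0.57 (percentile 0.44) in spleen of Asbt-/- hosts. In the small intestine pairs of Asbt+/+ and Asbt-/- hosts, the regulatory markers stood at -0.47 (percentile 2.39) and -0.22 (percentile 22.4), and effector cytokines at 0 (percentile 47.9) and -0.17 (percentile 27.1). Other lists also lay below percentile 2 or above 98. In spleen these were erythroid genes, at 0 in Asbt+/+ and 100 in Asbt-/- hosts, and NK and innate lymphoid genes, at 0.82 and 0.04. In spleen of Asbt+/+ hosts alone they were the hairpin target and multidrug transporter list (0.04), inhibitory receptors (0.13), heat shock (0.42), epithelium (99.25), cell cycle (99.89) and myeloid genes (100), and in spleen of Asbt-/- hosts alone CD4 T cell identity (99.02) and interferon-stimulated genes (99.93). In small intestine they were NK and innate lymphoid genes (0.5) and the type 1 helper programme (99.87) in Asbt+/+ hosts, and the type 17 helper programme (0.45) and myeloid genes (1.92) in Asbt-/- hosts.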

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

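The marker test for RNA of neutrophils and red blood cells, the test of the T cell RNA share and the split test of the regulatory T cell markers were chosen only after the results they concern were seen. The fit without both small intestine Asbt+/+ libraries was also added then. Of 54 groups of 4 libraries examined, 9 held a library far from the others by a gap test. Chance meets it in about 1 in 20 groups of normally distributed values. A gene with counts in only 1 of the 4 libraries always meets it, as Cd8b1 and Slc10a2 did. The hemoglobin share and the erythroid sum are largely the same transcripts. The 9 groups therefore cannot be set against that rate.

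In shMdr1 small intestine Asbt+/+, mitochondrial transcripts took 18.309% of counts, against 8.625% in the next small intestine library, and Rn18s-rs5 took 1.636%, against 0.485%. In shMdr1 spleen Asbt-/-, hemoglobin took 3.692%, against 0.554% in the next spleen library, and the summed CPM of the erythroid genes was 41588.6, against 5130.4. Among the small intestine libraries, shCD8 Asbt-/- stood apart with Abcb1b at 29.93 CPM (next 18.61), Cd8b1 at 2.394 CPM (others 0) and Hmox1 at 8.38 CPM (next 0.6419). In shCD8 spleen Asbt+/+, Cd8b1 reached 3.439 CPM and Hmox1 8.599 CPM. Slc10a2 stood at 1.436 CPM in shCD8 spleen Asbt-/- and 0.3962 CPM in shMdr1 small intestine Asbt-/-, from 3 counts and 1 count, with 0 in the other libraries of each tissue. Between tissues, the effect of the host on cell cycle genes differed by a median log2 of 2.432, the interaction called among 52 examined (limma's camera adjusted p = 8.14e-09, and adjusted p = 0.623 with an estimated correlation). Both Asbt+/+ libraries of its small intestine part stood apart, shMdr1 in mitochondrial share and shCD8 with 8456 genes detected. Within small intestine, the host call of this list was lost without shMdr1 Asbt+/+ or without shMdr1 Asbt-/-.

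Neutrophil and hemoglobin genes made up 9 of the 11 genes higher in spleen, among them S100a8 at 2759 ± 2036 CPM and Hbb-bs at 6369 ± 9973 CPM (mean ± SD, n = 4) in spleen. The shMdr1 spleen Asbt-/- library had 21280 CPM of Hbb-bs and the other spleen libraries 480.3 to 2470. A difference in library depth is argued against by the total counts, which ran only from 1685225 to 2767105. With such totals, thinning to the lowest could hardly have come out otherwise. It left the 9 genes at a median log2 fold change of -8.36 (SD 0.219 over 10 thinnings, -8.46 before). RNA of neutrophils and red blood cells in the spleen sorts is a candidate source that the markers leave open. Of 24 further markers below the threshold, 19 had a higher mean CPM in spleen, which is 79.2% and short of the 80% set for this source. The 4 without a count in any library cannot show a difference; of the other 20 the share is 95%. Retnlg had 40.9 against 0 CPM, some rest on few counts (Stfa1 1, Prtn3 4, Csf3r 7), and Mpo, at 0.749 against 3.09 CPM, went the other way. The sort for congenic CD4+ cells would remove such cells, and expression by the T cells themselves was not tested.

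The shCD8 small intestine Asbt+/+ library had 8456 genes detected. Shallower sequencing is argued against by its total of 2417913 counts, above the lowest total of 1685225. Thinning to the lowest total could therefore not bring it level. It left 8148.7 genes, where the other libraries had 10974.9 to 12845.6. A few genes taking most counts is argued against by 7952.3 genes without each library's 50 most abundant genes, where the others had at least 10833.2. Few RNA molecules entering amplification may contribute, since the SD of log2 deviations among its least abundant genes was 2.19 times that among its most abundant, although ratios of 2.72, 2.62 and 1.81 in the other small intestine libraries do not single it out. No biological explanation was tested, as there is 1 such library.

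The 14 regulatory T cell markers had a median log2 fold change of -0.668 with shMdr1, and none passed. A lower share of T cell RNA is argued against by the 14 CD4 T cell identity genes, at -0.042 (SE 0.082), short of the -0.334 that was set as its bound. Shallower shMdr1 libraries are argued against by total counts of 1685225 to 2767105 with shMdr1 and 2100582 to 2417913 with shCD8. With such totals, thinning to the lowest could hardly have come out otherwise. It left the markers at a median of -0.711 (SD 0.046). Chance is not excluded: of 35 splits of the 8 libraries into 4 and 4, 9 gave any of the lists a camera p as small (-log10 p 6.01 in the real grouping, highest other 14.74). The 35 include the splits by tissue and by host, which may hold real differences. Camera called the list with each library left out (adjusted p = 5.59e-07 to 0.00785), and the call was lost with an estimated correlation (adjusted p = 0.623) and with fry (0.662). No biological explanation was tested.

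Chance as the source of the tissue counts is argued against, but not excluded, by 35 splits of the 8 libraries. The real split gave 62 genes with 0 as the highest other, and 21 lists against 17. It ranked first for both, and 1 of 35 is the lowest share these splits can give. For the lists of the other comparisons the real split did not stand out. As many as 1 list for hairpins came from 30 of 35 splits (highest other 21), and as many as 2 for hosts from 16 of 35 (highest other 22). Those 35 include the splits by the other factors, so the highest values need not come from chance. Splits cannot test the 0 genes between hairpins and between hosts, since any split gives at least 0 (35 of 35 for each; highest other 66 and 65). The 66 and 65 genes came from the split by tissue. That split repeats the tissue comparison on the same libraries, without the hairpin or the host as covariate, and adds no separate support.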

How the results depend on the processing

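Fits without both small intestine Asbt+/+ libraries, with quality weights, without hemoglobin, mitochondrial and Rn18s-rs5 counts, and with a block for each matched library pair were chosen only after the results were seen. No pairing by animal was possible, since the labels do not say which libraries share an animal; the matched pairs are libraries alike in the other 2 factors.

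The 62 genes between tissues became 62 with DESeq2 size factors (61 shared), 73 with limma-voom (53 shared), 69 without covariates (51 shared), 54 with the block for each matched library pair (50 shared) and 58 without hemoglobin, mitochondrial and Rn18s-rs5 counts (58 shared). The count moved to 165 with no filter, 257 with DESeq2, 40 without both small intestine Asbt+/+ libraries, 116 with quality weights, and 12 to 145 when each library was left out. The cause was not tested.

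Between hairpins edgeR called 0 genes, against 9 with no filter, 3 with DESeq2 and 2 with quality weights (Cxcl3 and Ifitm2). Between hosts it called 0, against 14 with no filter, 6 with DESeq2, 6 with quality weights, and 0 to 4 when each library was left out. The tissue-dependent hairpin effect had 1 gene with DESeq2 and 1 to 2919 when each library was left out. The tissue-dependent host effect had 22 with DESeq2 and 0 to 3290 (2 to 3290 where it moved), and the host-dependent hairpin effect 3 with no filter, 3 with limma-voom and 0 to 769. The cause was not tested, except that leaving out a library in the fits by tissue leaves 1 residual degree of freedom, and a lone library is assumed to vary like the others.

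Within small intestine, hairpins differed in 26 genes with DESeq2, 7 in that tissue alone and 1 to 3773 with each library left out, and hosts in 65, 7 and 6 to 4139. Within spleen, hairpins differed in 3, 81 and 1 to 92, and hosts in 20, 149 and 1 to 151. Fits of 1 tissue alone have 1 residual degree of freedom.

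Of 21 lists called between tissues, 0 were called with an estimated correlation, 10 with fry, and 19 to 22 with each library left out. The 1 list between hairpins became 0 with an estimated correlation, 0 with fry, 4 without both small intestine Asbt+/+ libraries and 1 to 5 (2 to 5 where it moved) with each library left out. The 2 between hosts became 0, 0, 5 and 1 to 4, and 1 with the block for each matched library pair. The block moved no other count by over 1.5 times, with 0 genes between hairpins and 0 between hosts. The 2 between hosts in small intestine became 0 with an estimated correlation, 0 with fry and 1 to 2 with each library left out. The cell cycle list between tissues lost its call without both small intestine Asbt+/+ libraries (camera adjusted p = 0.955, which gives no direction). It was called with each library left out (1.65e-06 to 0.0466). Among values of named genes, the ratios of the pairs included, 2878 were counted as unchanged under an alternative. Of the rest, 419 passed only under it, 145 no longer passed and 0 reversed. Fold changes that passed in neither fit were counted as unchanged whatever their direction, so their reversals were not counted. Ratios of the pairs, which have no threshold, were compared by their counting interval.

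Depth limits genes near 3 counts, which is 1.18 to 1.93 CPM.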

Other observations

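The fit of the spleen libraries alone was planned; the genes named from it here were chosen after their values were seen. With 1 residual degree of freedom, edgeR called 81 genes between hairpins in spleen, 49 higher and 32 lower with shMdr1. The interferon-induced membrane protein genes Ifitm1 (15.2-fold), Ifitm2 (5.25-fold) and Ifitm3 (2.20-fold) were higher, as were the cytotoxic genes Ctsw (2.48-fold) and Klrk1 (7.81-fold), while Klrg1, a receptor gene of cytotoxic and regulatory lymphocytes, was 3.51-fold lower. The granzyme genes Gzmb and Gzmk went the other way. In the hairpin comparison of all 8 libraries they stood at log2 -0.66 and -0.78, lower in 4 of 4 pairs, and did not pass. Of 5 NK and innate lymphoid genes none were called in spleen alone, and 3 were lower adjusted over the list alone. Gzma was called 2.26-fold higher, but its pairs disagreed: 1037 CPM with shMdr1 against 156 with shCD8 in Asbt+/+ hosts, and 70.4 against 105 in Asbt-/- hosts. The cytokine genes Il17a (2.40-fold), Il4 (4.52-fold) and Il22 (2.30-fold), and Foxp3 (4.64-fold), Il2ra (4.39-fold) and Ikzf2 (2.05-fold) were lower. Of 14 regulatory T cell markers 5 were lower, and 7 adjusted over the list alone. Of 17 effector cytokines 4 were lower, and 6 adjusted over the list alone. Of 8 erythroid genes 3 were called higher, and 6 adjusted over the list alone (median log2 1.66), but the pairs of the 3 disagreed. With shMdr1 against shCD8, Hbb-bs had 1264 against 2501 CPM in Asbt+/+ and 21550 against 486 in Asbt-/- hosts, Hbb-bt 265 against 548 and 4733 against 135, and Car1 100.3 against 3.48 and 3.12 against 7.27. The neutrophil genes Camp (3.42-fold), Ngp (3.47-fold), Retnlg (4.04-fold) and Wfdc21 (2.46-fold) were higher. In Asbt+/+ hosts Camp had 586 against 572 CPM and Ngp 164 against 171, and in Asbt-/- hosts Retnlg had 13.1 against 21.3. Of 13 epithelial markers 3 were higher, and 4 adjusted over the list alone; Phgr1 and Krt8, 2 of the 3, had no counts in the Asbt-/- libraries. When the other diagonal of the 4 libraries replaced the host as covariate, edgeR called 0 genes between hairpins, with 335 at an unadjusted p under 0.05.

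Between hosts in spleen, the same fit called 149 genes, 76 higher and 73 lower in Asbt-/- hosts, and 3 with the diagonal as covariate. Of 30 cell cycle genes 9 were called lower, and 16 adjusted over the list alone, with none above 0, among them Cdk1 (2.86-fold), Ccna2 (2.50-fold) and Rrm2 (2.45-fold). The granule genes Gzma (4.63-fold) and Gzmb (3.05-fold) and the gamma delta receptor gene Tcrg-C2 (8.25-fold) were lower. Of 13 epithelial markers 5 were lower, and 6 adjusted over the list alone, with none above 0 (fitted median log2 -5.11). Several of them, such as Krt8, Krt19 and Reg3g, had no count in either Asbt-/- spleen library, so this median is not a measured fold. Of 19 myeloid genes 4 were lower, and 7 adjusted over the list alone (median log2 -1.04). Kdm6b (3.84-fold) was higher, and so were 10 mitochondrial genes, with 0 lower. Rn18s-rs5 took 2.346% of counts in shMdr1 and 1.596% in shCD8 spleen of Asbt-/- hosts, against 0.393 and 0.34% in Asbt+/+ hosts. Of 23 ribosomal protein genes 0 were called and 2 lay above 0 (median log2 -0.301).

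With shMdr1 and shCD8, Tcrg-C2 had 353 and 238 counts in small intestine of Asbt+/+ hosts, 79 and 163 in small intestine of Asbt-/- hosts, 263 and 48 in spleen of Asbt+/+ hosts and 5 and 17 in spleen of Asbt-/- hosts. In the same order Klrd1, a receptor gene of cytotoxic lymphocytes, had 518 and 358, 208 and 171, 508 and 84, and 39 and 108 counts. These genes, too, were chosen after their values were seen.

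Trbv12-2 was the most abundant T cell receptor beta segment in 8 of 8 libraries. Its share was 20.7 to 59.2% of only 213 to 622 beta segment counts per library. Alpha chain segments were detected in numbers from 8, in shCD8 small intestine Asbt+/+, to 32, in both Asbt-/- spleen libraries. These numbers rest on 54 to 192 alpha segment counts per library, and the library with 8 also had the fewest genes detected. Log2 ratios of shMdr1 over shCD8 correlated across 10000 genes between pairs with Spearman coefficients of -0.006 to 0.119.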
